A study of Mus musculus with 90 samples.

How the data were processed

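Expression was measured in 45 mouse tissues with 2 arrays per tissue, 90 arrays in all, and all of them were used. Per the labels the RNA was total RNA, extracted and labelled by the array maker's instructions, and the authors computed 1 signal per probe set with the Affymetrix MAS4 algorithm. The deposited values are an intensity on a linear scale, the MAS4 signal, which is below 0 where mismatch probes were brighter than matching ones. The deposited values ran from -3845.7 to 49188.75, and the median share of probe sets below 0 was 26.9 percent per array. The trimmed means of the deposited arrays lay between 229.7 and 244.5 and their medians between 106.7 and 138.6, so that the arrays had been brought near a common level before deposit. The scaling target, detection calls and image files are not given in the sources used here. The labels give background averages of 205.92 to 463.21, and for both frontal cortex arrays the same background statistics, although their values differed. Array names fall into 6 series, whose meaning is not given in the sources used here; the arrays of 33 tissues lie in 1 series and those of 12 tissues in more than 1.

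Each array was scaled to a trimmed mean of 200 with 2 percent trimmed at each end (factors of 0.818 to 0.871), values below 50 were set to 50, and the log2 was taken. Mean signals in the text are scaled values without the floor, and fold changes are 2 to the power of the difference in mean log2 with the floor, so they are not ratios of the mean signals. A fold is written as "at least" where every array on the lower side was at the floor. Of 10043 probe sets, 66 controls were left out. Gene symbols came from the platform's annotation table, checked against a RefSeq table of the mouse genome: 8724 probe sets named 1 gene, 346 several and 907 none, for 7417 genes, and 8710 matched a gene of the RefSeq table. A probe set was tested if its mean signal was at least 200 in at least 1 tissue, which left 7623.

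Tests used limma 3.58.1 in R 4.3.3 with eBayes and a mean trend. In the 5 class comparisons the arrays of a tissue were averaged, so that a tissue was 1 replicate. Tissue pairs, brain regions and single tissues were contrasts in 1 fit of 90 arrays with 45 tissue means, 45 residual and 3.39 prior degrees of freedom. All tests were two-sided. P-values were adjusted by Benjamini and Hochberg within each comparison. Counts of probe sets needed an adjusted p below 0.05 and a log2 difference of at least 1. Tissue-enriched probe sets needed a log2 difference of at least 2 from the mean of the other 44 tissues and a tissue signal of at least 200. Named genes and list members needed the adjusted p alone, with no minimum log2 difference.

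The groups, tests, 58 gene lists, settings to vary and the rule for naming genes were chosen before the data were examined. The rule named, among probe sets of 1 gene that passed and had a mean signal of at least 200 on the higher side, the 10 largest log2 differences per direction in a class comparison, the 6 largest per direction in a tissue pair and the 3 largest increases per brain region and per tissue, with 1 probe set per gene. Of the 3 per tissue the largest is given. From each list the members with the largest differences were named, with members that passed against the list's direction. List members are represented by the probe set with the highest mean log2 value, which can differ from that of a named gene. Lists were tested with camera in limma at a preset correlation of 0.01, with an estimated correlation as the alternative, and the 104 list tests were adjusted as 1 family. With the estimated correlation 85 results kept their side of the threshold, many at a far larger p, and 19 calls were lost.

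The limma steps were tested on simulated data with 200 of 7623 probe sets changed. Of 4-fold changes, unlike most folds not limited by the floor, 97.1 percent were called for CNS, 91.5 for ganglia and 83.3 for lymphoid tissues. The share was 84.6 for digestive tract, 73.8 for epidermal tissues and 85.3 for a tissue pair. At 2-fold these shares were 39.7, 31.7, 22, 23.5, 33.3 and 21.7 percent, so small differences were often missed. Between 3 and 10 unchanged probe sets were called.

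The alternatives were floors of 20 and 100, values as deposited, quantile normalization, no filter, no mean trend, the array-name series as a block, arrays as replicates, the mean of all probe sets of a gene, other signal levels for breadth, and leaving out each array or each tissue of the smaller class. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.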

Results

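RNA from 45 mouse tissues was measured on 90 short-oligonucleotide expression arrays, with 2 arrays per tissue and 10043 probe sets per array. The question given by the series is which genes each tissue expresses and how expression differs across the body. The tissues fell into brain and spinal cord (10 tissues, called CNS here), sensory ganglia (2), lymphoid and marrow tissues (4: thymus, spleen, lymph node and bone marrow), digestive tract (3: stomach, small and large intestine), epidermal tissues (3: epidermis, snout epidermis and tongue epidermis) and other tissues. The eye, a neural and non-neural mixture, entered no class comparison. Per the labels the mice were C57BL/6, most samples were pools of 4 males and 3 females aged 8 to 11 weeks, and placenta, mammary gland and umbilical cord came from embryonic day 18 of pregnancy. The labels do not say that the arrays of a tissue came from separate pools, so they may be technical replicates and every p-value measures only the spread between these samples. All signals below are scaled to a trimmed mean of 200, and all fold changes are on the log2 scale after a floor of 50, so a fold against tissues near the floor depends on that floor.

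The arrays of a tissue resembled each other more than they resembled other tissues. The correlation between the arrays of a tissue, across probe sets, had a median of 0.942, from 0.782 in salivary gland to 0.963 in bladder, against a median of 0.736 over 3960 pairs of arrays from different tissues. Probe sets are not independent replicates, so these correlations carry no p-value. Of the 90 arrays, 77 were closest to their own partner and 13 to an array of another tissue. The correlation was below 0.9 in salivary gland, ovary (0.86), lung (0.864), tongue epidermis (0.868), large intestine (0.875) and spleen (0.879).

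**Figure D1:**
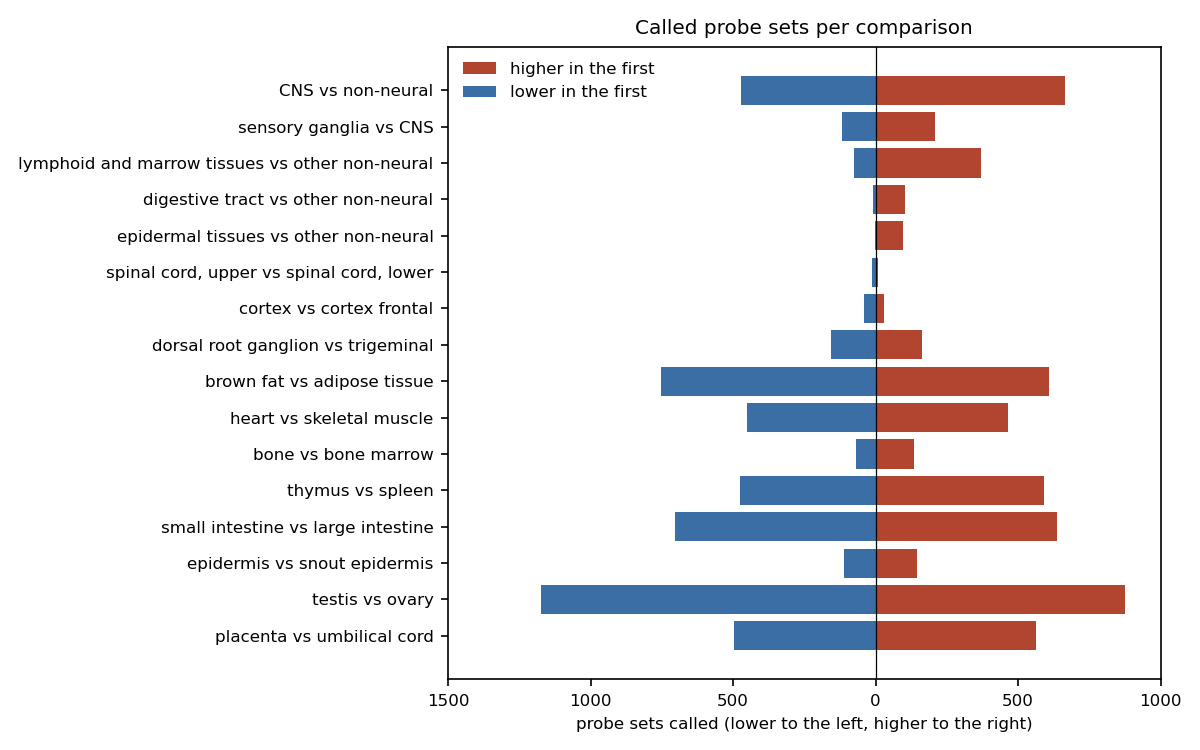
Number of probe sets called in each of 16 comparisons of tissue classes and tissue pairs (adjusted p below 0.05 and a log2 difference of at least 1). Bars to the right count probe sets higher in the first tissue or class, bars to the left those lower in it; testis against ovary had the most (876 and 1174) and upper against lower spinal cord the fewest (8 and 14).

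The comparison of CNS with non-neural tissues asked what sets nervous tissue apart from the rest of the body. Snap25, which drives the fusion of synaptic vesicles, was at least 92.4-fold higher in CNS (log2 6.53 ± 0.10 SE, adjusted p = 6.0e-42), with a mean signal of 4840 ± 1060 (SD, n = 10 tissues) against -375 ± 88.6 (SD, n = 32). Dnm1, the neuronal dynamin of endocytosis, was 49.3-fold higher (log2 5.62 ± 0.26 SE, adjusted p = 1.5e-22), and Ptgds, a prostaglandin D synthase of the meninges and glia, was 46.7-fold higher (log2 5.55 ± 0.40 SE, adjusted p = 9.4e-16). The glutamate receptor subunit Gria2 was at least 36.3-fold higher and Slc32a1, the vesicular transporter of GABA and glycine, at least 33.1-fold higher. Ncdn (47.1-fold), Tspyl4 (39.2-fold), Rtn1 (37.9-fold), Eno2 (34.1-fold) and Slc22a17 (29.9-fold) completed the 10 largest increases. Among the 10 largest decreases, H2-K2, a major histocompatibility gene, was 24.4-fold lower (log2 -4.61 ± 0.53 SE, adjusted p = 1.5e-09) and Dcn, the collagen-binding proteoglycan decorin, 15.7-fold lower, at 647 ± 997 (SD, n = 10 tissues) against 6320 ± 4320 (n = 32). Anxa2 was 15.9-fold lower, Col1a2 12.2-fold, Mknk2 11-fold, Anxa1 10.4-fold, Col1a1 9.89-fold and Serp1 9.38-fold, while H2-K1 was at least 12-fold and H2-Aa at least 10.5-fold lower.

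Gene groups fixed in advance were tested in the same comparison. All 16 tested neuronal and synaptic genes rose, also when adjusted over the list alone (set test adjusted p = 4.4e-23), with Camk2b at log2 4.79 ± 0.28 SE and Vamp2 at 3.51 ± 0.25. Of 8 transmitter genes 6 rose, and 8 did when adjusted over the list alone (adjusted p = 3.6e-12), among them Gad1 (4.84 ± 0.18) and Gria1 (3.69 ± 0.27). Of 7 myelin genes 6 rose, also over the list alone (adjusted p = 1.2e-06), such as Cldn11 (2.84 ± 0.24) and Mbp (2.67 ± 0.19). All 7 astrocyte genes rose on both scales (adjusted p = 2.1e-05), with Aqp4 at 2.66 ± 0.30 and Gfap at 2.46 ± 0.25. Of 10 extracellular matrix genes 8 fell, also adjusted over the list alone (adjusted p = 4.6e-05, but 0.16 with an estimated correlation). Col3a1 fell by 3.03 ± 0.50 and Postn by 2.69 ± 0.50 on the log2 scale. Of 11 antigen-presentation genes 7 fell and 9 did over the list alone (adjusted p = 4.6e-06, but 0.14 with an estimated correlation). B2m was at -2.98 ± 0.40 and H2-D1 at -2.81 ± 0.33. Of 27 ribosomal protein genes 17 fell and Rpl38 rose (0.42), or 17 and 3 adjusted over the list alone, with Rps18 at -1.72 ± 0.21 (adjusted p = 9.7e-06, but adjusted p = 0.18 with an estimated correlation). Of 19 proliferation genes Cdc20, Mcm4 and Mcm5 fell, or 2 over the list alone (adjusted p = 0.014, but 0.52 with an estimated correlation). Of 8 smooth muscle genes Acta2 (-3.15 ± 0.82) and Tagln (-1.81 ± 0.54) fell on both scales (adjusted p = 0.036, but adjusted p = 0.41 with an estimated correlation). Eng (-2.15 ± 0.54) and Cdh5 (-1.46 ± 0.50) fell among 9 endothelial genes on both scales (adjusted p = 0.2). None of 8 erythroid genes passed on either scale (adjusted p = 0.6).

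Of the 7623 probe sets tested by limma on tissue means, 665 were higher and 471 lower in CNS. Arrays belong to 6 array-name series, and within series 1 to 5 the called probe sets kept their direction in 99.1, 93.3, 99.4, 99.6 and 99.6 percent of cases. The same arrays had made the calls, here and in the other class comparisons, so a high share is partly built in.

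Sensory ganglia were set against CNS to find what peripheral sensory neurons and their companions express beyond central tissue. Anxa2, a calcium-dependent membrane-binding protein, was 84.9-fold higher (log2 6.41 ± 0.83 SE, adjusted p = 0.0011), at 6090 ± 272 (SD, n = 2 tissues) against -118 ± 327 (n = 10). Fxyd2, a regulator of the sodium pump, was 62.9-fold higher (5.98 ± 0.61), Sncg, or gamma-synuclein, 47.9-fold, and Scn10a, the voltage-gated sodium channel of pain-sensing neurons, 23.2-fold (4.54 ± 0.26, adjusted p = 1.5e-06). Fstl1 (39.3-fold), S100a10 (38.6-fold), Akap12 (27.9-fold), Dcn (27.7-fold), S100a6 (21.1-fold) and Cd9 (15.9-fold) were also higher. In the other direction, Camk2b, a calcium-dependent kinase of forebrain synapses, was at least 34.4-fold lower (-5.10 ± 0.61, adjusted p = 6.6e-04) and Gad1, which makes GABA, at least 28.6-fold lower. Gria2 (26.7-fold), Slc32a1 (25.3-fold), Cx3cl1 (18.7-fold), Ramp1 (10.4-fold), Dtx1 (8.3-fold), Bcan (at least 7.66-fold), Dusp8 (at least 6.91-fold) and Sf3a2 (6.68-fold) were lower as well.

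Among the ganglion lists, 4 of 6 sensory neuron genes rose, also adjusted over the list alone (adjusted p = 1.5e-08), with Prph, a filament protein of peripheral neurons, at 2.66 ± 0.29 and Isl1 at 206 ± 19.1 (SD, n = 2 tissues) against 19.3 ± 23.3 (n = 10). Of 11 antigen-presentation genes 5 rose and 6 over the list alone (adjusted p = 4.3e-04), B2m at 1.94 ± 0.42 and H2-Eb1 at 1.83 ± 0.39. Dcn, Lum (1.53 ± 0.30) and Postn (1.32 ± 0.06) rose among 10 matrix genes on both scales (adjusted p = 6.1e-04, but adjusted p = 0.15 with an estimated correlation). Of 8 transmitter genes 3 fell and 5 over the list alone (adjusted p = 1.3e-05), while Gja1 (-2.27 ± 0.29) and Glul (-1.18 ± 0.21) fell among 7 astrocyte genes on both scales (adjusted p = 0.054). Of 16 neuronal genes Camk2b, Map2 (-2.05) and Sncb (-1.10) fell and Stmn2 rose (1.43 ± 0.25), or 3 and 3 adjusted over the list alone (adjusted p = 0.31). Pmp22, a protein of peripheral myelin, rose (3.01 ± 0.79) as 1 of 4 Schwann cell genes on both scales (adjusted p = 0.21). None of 7 myelin genes passed over all probe sets, and 1 was lower adjusted over the list alone, with Cldn11 at -2.59 ± 0.77 (adjusted p = 0.13). None of 8 pituitary genes passed over all probe sets, 4 over the list alone (adjusted p = 0.0059, but 0.16 with an estimated correlation). Gh was at 3.85 ± 1.37. In dorsal root ganglion Gh, Prl, Pomc and Cga stayed below a mean of 200, while Lhb was at 780 and 743 and Ghrhr at 660 and 619. None of 12 fast skeletal muscle genes passed on either scale (adjusted p = 0.62).

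By limma on tissue means 209 probe sets were higher and 118 lower in ganglia, and 327 of 327 kept their direction within series 4, where trigeminal was the ganglion. With the series as covariates all named genes except Scn10a and Dtx1 lost the call. Of these tissues only dorsal root ganglion lay in series 6, so that fit rested on trigeminal alone. In that fit Anxa2 was at 7.34 ± 2.66, Fxyd2 at 6.30 ± 1.54 and Sncg at 5.68 ± 2.40 (from 5.58 ± 0.82), no smaller but with wider standard errors. Only Bcan shrank by much, from -2.94 ± 0.75 to -1.43 ± 1.16, so the other lost calls do not show that the series made the differences. Without dorsal root ganglion Dcn (4.85), S100a6 (4.16), Cx3cl1 (-5.02), Bcan (-2.94) and Sf3a2 (-2.86) no longer passed. Without trigeminal Dcn (4.73), Cx3cl1 (-3.43), Bcan (-2.94) and Sf3a2 (-2.62) no longer passed. These fits held 1 ganglion in place of 2, and most of the differences stayed about as large.

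Lymphoid and marrow tissues were compared with the other non-neural tissues, bone left out because it holds marrow. Coro1a, an actin regulator of blood cells, was 46.6-fold higher (log2 5.54 ± 0.58 SE, adjusted p = 1.0e-07), at 3320 ± 1230 (SD, n = 4 tissues) against -226 ± 399 (n = 27). Ltb, the lymphotoxin that organizes lymphoid tissue, was 21.5-fold higher (4.43 ± 0.67), Cd53, a tetraspanin of white blood cells, 20.2-fold (4.34 ± 0.59), and Ighm, the heavy chain of immunoglobulin M, 18.2-fold (4.19 ± 0.67). Laptm5 (18.5-fold), Igkv6-23 (17.3-fold), Ptprc (14-fold), Vcam1 (13.4-fold), Cytip (12.6-fold) and Cyba (12.5-fold) followed. The lower genes were less far apart: Uqcr11, a subunit of respiratory complex III, was 10.8-fold lower (-3.44 ± 0.81, adjusted p = 0.0066) and Mt1, a metal-binding metallothionein, 10.7-fold lower (-3.42 ± 0.62, adjusted p = 3.8e-04). Dbi (7.06-fold), Chpt1 (5.93-fold), Lmo7 (5.56-fold), Mcfd2 (5.55-fold), Cpe and Col3a1 (5.28-fold each), Nckap1 (5.1-fold) and Cttn (4.75-fold) were also lower.

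Of 15 T cell genes 7 rose and 12 over the list alone (adjusted p = 5.3e-09, or 0.043 with an estimated correlation). Cd3d was at 2.39 ± 0.36. Of 12 B cell genes 7 rose and 10 over the list alone (adjusted p = 1.7e-08), with Cd79a at 3.45 ± 0.75 and Blk at 2.16 ± 0.49. Of 11 antigen-presentation genes 8 rose on both scales (adjusted p = 2.8e-09), Psmb9 at 2.61 ± 0.39 and H2-Aa at 3.33 ± 0.98. Of 19 proliferation genes 9 rose and 16 when adjusted over the list alone (adjusted p = 2.6e-12), Mcm5 at 3.58 ± 0.50 and Pcna at 2.16 ± 0.53. S100a8 (3.25 ± 0.73) and Camp (1.57 ± 0.42) rose among 12 granulocyte genes, 7 over the list alone (adjusted p = 2.7e-05, but adjusted p = 0.16 with an estimated correlation). Slc4a1, the anion exchanger of red cells, rose (2.34 ± 0.56) among 8 erythroid genes, 4 over the list alone (adjusted p = 0.0011, but adjusted p = 0.17 with an estimated correlation). Col3a1 fell among 10 matrix genes, 2 over the list alone (adjusted p = 0.0015, but 0.29 with an estimated correlation). None of 7 brown fat genes passed on either scale (adjusted p = 0.097), and none of 6 pancreatic acinar genes over all probe sets, 1 over the list alone (adjusted p = 0.095).

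By limma 369 probe sets were higher and 76 lower, and within series 3 to 6 the called probe sets kept their direction in 97.3, 96.4, 92.1 and 88.3 percent of cases. The lower count was 46 without thymus, 33 without spleen, 50 without lymph node and 32 without bone marrow. These fits have less power, and most differences that lost the call stayed about as large. Col3a1 lost it without thymus (-2.54, adjusted p = 0.081), spleen (-2.51, 0.084) or bone marrow (-1.69, 0.29), Cpe without any of these 3 (-2.27 to -2.20, adjusted p = 0.14 to 0.15) and Cttn without any of the 4 (-2.49 to -2.17, adjusted p = 0.065 to 0.13). Chpt1 (-2.54 in each fit, adjusted p = 0.06 to 0.061) and Lmo7 (-2.50 to -2.21, adjusted p = 0.075 to 0.13) lost it without spleen, lymph node or bone marrow. Igkv6-23 lost it without spleen (3.88, adjusted p = 0.075) or lymph node (3.76, 0.088), Dbi without spleen (-2.72, 0.061) or bone marrow (-2.34, 0.11) and Mcfd2 without bone marrow (-2.39, 0.05). A floor of 100 ended the call of Chpt1 (-1.73, adjusted p = 0.093), Mcfd2 (-1.78, 0.065), Cpe (-1.78, 0.13), Col3a1 (-2.20, 0.056) and Cttn (-1.59, 0.053). With the series as covariates Lmo7 (-2.22 ± 0.69, from -2.47 ± 0.71) and Col3a1 (-2.43 ± 0.79, from -2.40 ± 0.73) lost it.

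The digestive tract was set against the other non-neural tissues to find genes higher in the gut, where a class mean can rest on 1 tissue. Agr2, a disulfide isomerase of mucus-secreting cells, was 43.9-fold higher (log2 5.45 ± 0.73 SE, adjusted p = 1.3e-05), at 5950 ± 7490 (SD, n = 3 tissues) against 104 ± 540 (n = 29). Spink4, a protease inhibitor of goblet cells, was 38.4-fold higher (5.26 ± 0.62), Fabp2, the fatty acid carrier of enterocytes, 30.5-fold (4.93 ± 0.73), and Sult1b1, a sulfotransferase, 25.5-fold (4.67 ± 0.24, adjusted p = 1.0e-15). Akr1c13 (24.3-fold), Sprr2i (23.4-fold), Tff3 (19.5-fold), Tspan8 (17.6-fold), Krt20 (17-fold) and Sprr2b (16.7-fold) were higher too. Few genes were lower: Atxn10 (4.48-fold, -2.16 ± 0.46), Rdx (3.94-fold, -1.98 ± 0.31), Qk (3.83-fold), Psmd4 (3.59-fold), Smoc1 (3.39-fold), Wnk1 (2.51-fold), Mmp11 (2.3-fold) and Stat3 (1.7-fold).

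Of 14 absorptive intestine genes 6 rose and 11 over the list alone (adjusted p = 9.1e-25), with Vil1, the microvillus protein villin, at 3.75 ± 0.51 and Apoa4 at 3.45 ± 0.68. Tff3 (4.29 ± 0.87), Reg3b (3.45 ± 0.76) and Itln1 (3.42 ± 0.51) rose among 6 Paneth and goblet cell genes on both scales (adjusted p = 6.1e-09). Of 7 stomach genes 4 rose and 6 over the list alone (adjusted p = 2.4e-09), such as Cblif, or intrinsic factor (2.88 ± 0.67), and Atp4b of the acid pump (2.82 ± 0.74), and these 2 came from stomach alone (means of 13600 and 17600, against 96.2 and -225 in small and 118 and -247 in large intestine). No member passed on either scale in the lists for large intestine (5 genes, adjusted p = 0.073), pancreatic acinar cells (6, adjusted p = 0.57), B cells (12, adjusted p = 0.58), T cells (15, adjusted p = 0.15) and antigen presentation (11, adjusted p = 0.53). None of 8 smooth muscle genes passed on either scale although the set test did (adjusted p = 0.0035, but 0.26 with an estimated correlation). Cnn1 was at 2.48 ± 1.18 and Acta2 at 2.44 ± 1.53.

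By limma 103 probe sets were higher and 9 lower, and 99.1 and 91.1 percent of them kept their direction within series 1 and 3. The lower count was 19 without stomach, 5 without replicate 1 and 25 without replicate 2 of every tissue. Leaving out 1 of the 3 tissues ended several calls. Without stomach these were Sprr2i (4.07, adjusted p = 0.068), Smoc1 (-1.45, 0.11) and Mmp11 (-1.02, 0.28). Without small intestine they were Tff3 (3.10, adjusted p = 0.17), Atxn10 (-1.57, 0.22), Qk (-1.55, 0.2), Wnk1 (-1.06, 0.35) and Stat3 (-0.73, 0.2). Without large intestine they were Sprr2i (4.17, adjusted p = 0.077), Tff3 (2.93, 0.2), Psmd4 (-1.42, 0.23), Wnk1 (-1.40, 0.097), Mmp11 (-0.74, 0.61) and Stat3 (-0.68, 0.25). With the series as covariates the counts were 48 and 0, and Sprr2i (4.08 ± 1.26, adjusted p = 0.18) and all named lower genes lost the call with wider standard errors. Differences stayed about as large for Atxn10 (-2.08 ± 0.60), Qk (-1.89 ± 0.59), Psmd4 (-1.87 ± 0.51), Wnk1 (-1.44 ± 0.45) and Mmp11 (-1.22 ± 0.40), and were somewhat smaller for Rdx (-1.66 ± 0.41), Smoc1 (-1.45 ± 0.48) and Stat3 (-0.64 ± 0.25).

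Epidermal tissues were compared with the other non-neural tissues, digits left out because they carry skin. Krtdap, a protein of differentiating keratinocytes, was 124-fold higher (log2 6.96 ± 0.99 SE, adjusted p = 1.9e-05), at 10400 ± 1430 (SD, n = 3 tissues) against 395 ± 1620 (n = 28). Crct1, encoded in the epidermal differentiation complex, was 82.8-fold higher (6.37 ± 0.81) and Krt10, the keratin of suprabasal cells, 71.2-fold (6.15 ± 0.85). Krt17, a keratin of hair follicles, was 32.6-fold higher (5.03 ± 0.30, adjusted p = 1.8e-13) and Pkp1, a desmosome protein, 29.6-fold (4.89 ± 0.58). Mt4 (39.8-fold), Calm4 (38.9-fold), Psapl1 (33.2-fold), Anxa8 (27.4-fold) and Lgals7 (27.2-fold) were also higher. The single lower probe set was Strn4, 4.66-fold lower (-2.22 ± 0.54, adjusted p = 0.025).

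Of 18 keratinocyte genes 11 rose and 14 over the list alone (adjusted p = 5.8e-42), with Sfn at 4.45 ± 0.75 and Flg, the filaggrin precursor, at 3.83. Of 7 hair genes 4 rose and 5 over the list alone (adjusted p = 2.0e-12), with Krt31 at 3.55 ± 0.39 and Krt81 at 3.22 ± 0.52. None of 12 fast skeletal muscle genes passed over all probe sets and 9 did over the list alone. Their set test passed (adjusted p = 1.7e-13, and 0.044 with an estimated correlation of 0.851). Acta1 was at 13300 ± 4390 (SD, n = 3 tissues) against 3630 ± 7470 (n = 28). Elovl3 rose (0.98 ± 0.24) as 1 of 7 brown fat genes on both scales (adjusted p = 0.13). No member of the lists for antigen presentation (11 genes, adjusted p = 0.73) and proliferation (19, adjusted p = 0.49) passed on either scale. Nor did any of 10 matrix genes, with Col1a2 at 1.96 ± 1.34 (adjusted p = 1.0e-03, but 0.26 with an estimated correlation).

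By limma 95 probe sets were higher and 1 lower, and 100 percent of them kept their direction within series 4 but 68.8 percent within series 5, which held 1 epidermal array. That was tongue epidermis array 2, which was closest to an array of trachea and read the airway gene Scgb1a1 at 14300, against -71 on array 1. The higher count was 50 without snout epidermis and 62 without replicate 1 of every tissue. Strn4 lost its call without epidermis (-2.23, adjusted p = 0.16), snout epidermis (-2.19, 0.22) or tongue epidermis (-2.23, 0.15), and with a floor of 100 (-1.53, 0.12). With the series as covariates the counts were 60 and 0, and Strn4 was at -2.27 ± 0.65 (adjusted p = 0.15).

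Tissue pairs were compared with 2 arrays each, using 1 spread per probe set estimated by limma over all 45 tissues. That spread is too small for probe sets near the floor in most tissues, such as those of Bmp15, Inha, Crisp2, Dlx1 and Avp. Their very small standard errors or p-values, here and in the CNS regions, partly come from the floor. Upper and lower spinal cord differed least. Klk6, a protease of oligodendrocytes, was 6.79-fold higher in the upper cord (log2 2.76 ± 0.48 SE, adjusted p = 5.5e-04), at 536 ± 91.7 (SD, n = 2 arrays) against 81.4 ± 58.5 (n = 2), and Ugt8a, which makes the galactolipids of myelin, at least 4.89-fold higher (2.29 ± 0.47). Anln (at least 4.42-fold, adjusted p = 5.6e-06), Vamp1 (3.38-fold), Gbf1 (2.59-fold) and Mobp (2.33-fold) were higher as well. S100a9 and S100a8, which form the calprotectin of neutrophils, were 15.4-fold (-3.94 ± 0.59) and 6.06-fold (-2.60 ± 0.59) lower in the upper cord, as were Anxa2 (7.19-fold), Ngp, a granule protein of neutrophils (at least 5.6-fold), Mfap5 (3.82-fold) and Wdr6 (3.34-fold). Ugt8a was the only 1 of 7 myelin genes to rise on either scale (adjusted p = 1.1e-07), with Cldn11 at 0.70 ± 0.31. Among 4 Schwann cell genes Pmp22 fell on both scales (-1.71 ± 0.24, adjusted p = 0.049, but 0.12 with an estimated correlation). The list median was 0.17 and the mean -0.16. Of 16 anterior Hox genes Hoxa7 rose on both scales (0.85 ± 0.20, adjusted p = 0.21), and none passed on either scale among 7 posterior Hox genes (adjusted p = 0.27) and 16 neuronal genes (adjusted p = 0.31). In all 8 probe sets were higher and 14 lower. Lower cord array 1 carried the neutrophil signal: without it Ngp was 0.00, S100a8 -1.48, Vamp1 0.06 and Mobp 0.45. S100a9 (-2.54), Anxa2 (-2.48), Mfap5 (-1.38) and Ugt8a (2.29) also lost the call. Without lower cord array 2 the counts were 18 and 59 and Gbf1 (1.13, adjusted p = 0.086) and Wdr6 (-1.46, 0.17) lost the call. Without upper cord array 1 they were 4 and 8. There Ugt8a (2.17), Vamp1 (1.60), Mobp (1.18), S100a8 (-2.60), Ngp (-2.49), Mfap5 (-1.59) and Gbf1 (1.37) lost the call. Without upper cord array 2 Ugt8a (2.41), Mobp (1.26), S100a8 (-2.60), Ngp (-2.49), Anxa2 (-2.62), Gbf1 (1.38) and Wdr6 (-1.21) lost it. Klk6 and Anln kept the call in each of these 4 fits. A floor of 20 ended the call of Klk6 (2.92, adjusted p = 0.19), Ugt8a (3.27, 0.12), Mobp (1.22, 0.23), S100a8 (-2.60, 0.19), Mfap5 (-1.93, 0.84) and Wdr6 (-2.40, 0.2), at differences no smaller than before.

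Cortex and frontal cortex were compared as parts of the same brain structure. Scgb1b27, a secretoglobin, was 64.4-fold higher in cortex (log2 6.01 ± 0.68 SE, adjusted p = 1.5e-08), at 7040 ± 117 (SD, n = 2 arrays) against 129 ± 155 (n = 2), and Mucl2, a salivary mucin-like protein, 60.1-fold higher (5.91 ± 0.66). Prol1 (18.3-fold), Klk1, or glandular kallikrein (16.7-fold), Bpifa2, a secreted protein of the parotid (15.7-fold), and Pip, the prolactin-inducible protein (at least 13.6-fold), were higher as well. Gstm3 was at least 8.54-fold lower (-3.09 ± 0.72), Mobp, a myelin protein, 5.6-fold lower (-2.48 ± 0.28, adjusted p = 1.5e-08), and Nacc2 (at least 5.67-fold), Cramp1l (at least 5.21-fold), Hp (5.14-fold) and Ccl22 (4.77-fold) were lower too. Of 7 myelin genes Mag fell (-1.05 ± 0.26), or 3 adjusted over the list alone (adjusted p = 3.9e-05). Tbr1, a transcription factor of cortical projection neurons, rose (1.15 ± 0.22) as 1 of 6 cortical and hippocampal genes on both scales (adjusted p = 0.53). None of 16 neuronal genes passed on either scale (adjusted p = 0.89, median 0.06 with the set test pointing down), nor any of 4 striatal genes (adjusted p = 0.89). In all 29 probe sets were higher and 39 lower, or 25 lower with the array-name series as a block, where Gstm3 (-3.09 ± 0.72 before and -2.64 ± 1.07 in the block), Cramp1l (-2.38 ± 0.38 and -2.22 ± 0.57), Ccl22 (-2.25 ± 0.52 and -1.97 ± 0.79) and Hp (-2.36 ± 0.62 and -1.48 ± 0.89) lost the call. Over the tissue pairs and CNS regions the block ended the call of 30 named genes, all with a wider standard error, and 23 of them kept at least 66 percent of the log2 difference. Hp lost it without cortex array 2 (-1.67) or either frontal array (-2.32 and -2.41). Gstm3 lost it without any of the 4 arrays (-3.36 to -2.82), and Ccl22 without cortex array 1 (-1.77) or either frontal array (-2.35 and -2.16). A floor of 20 ended the call of Hp (-2.45, adjusted p = 0.064), and a floor of 100 those of Hp (-1.86, 0.096) and Gstm3 (-2.09, 0.058).

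Dorsal root ganglion and trigeminal tissue, the sensory ganglia of body and face, were compared next. Gh, or growth hormone, was 178-fold lower in dorsal root ganglion (log2 -7.48 ± 0.45 SE, adjusted p = 4.1e-18), at 110 ± 5.8 (SD, n = 2 arrays) against 19900 ± 4640 (n = 2), and Prl, or prolactin, 79.5-fold lower (-6.31 ± 0.77). Ptgds was at least 53.6-fold, Pomc, the precursor of corticotropin, at least 12.3-fold, Nnat 11.9-fold, and Cga, the alpha subunit of pituitary glycoprotein hormones, at least 11.8-fold lower. Get4 was 8.9-fold higher in dorsal root ganglion (3.15 ± 0.39, adjusted p = 7.8e-08), followed by Qsox1 (at least 7.85-fold), Acvrl1 (7.74-fold), Pacsin1 (7.56-fold), F2r (at least 7.32-fold) and Tex261 (7.04-fold). Of 8 pituitary genes 4 fell and 5 over the list alone (adjusted p = 3.1e-12). Scn10a rose (1.48 ± 0.21) among 6 sensory neuron genes, 2 over the list alone (adjusted p = 0.011). Pmp22 fell (-0.85 ± 0.24) among 4 Schwann cell genes on both scales (adjusted p = 0.023, but 0.07 with an estimated correlation). Among 16 anterior Hox genes Hoxa5 rose (0.96 ± 0.22) and Hoxb3 fell (-2.90 ± 0.74), or 2 and 1 over the list alone (adjusted p = 0.88, list mean -0.13, median 0 and a set test pointing up). None of 7 posterior Hox genes passed over all probe sets, 1 over the list alone (adjusted p = 0.078), and none of 12 fast skeletal muscle genes on either scale (adjusted p = 0.56).

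Between these ganglia 162 probe sets were higher and 155 lower, but 29 and 26 with the array-name series as a block, where 7 named genes lost the call. Dorsal root ganglion lies in series 6, which only gall bladder and ovary link to another series. The block's shift here rests on their arrays, so a lost call does not show equal ganglia. The estimate shrank most for Acvrl1 (2.95 ± 0.85 before and -0.41 ± 1.37 in the block) and F2r (2.87 ± 0.78 and 0.04 ± 1.28) and less for Get4 (3.15 ± 0.39 and 1.40 ± 0.54) and Qsox1 (2.97 ± 0.75 and 1.86 ± 1.26). It stayed large, with a wider standard error, for Tex261 (2.82 ± 0.75 and 3.43 ± 1.23), Pomc (-3.62 ± 0.76 and -3.18 ± 1.38, adjusted p = 0.34) and Nnat (-3.58 ± 0.58 and -3.14 ± 1.03, adjusted p = 0.16). The counts were 53 and 53 without dorsal root ganglion array 1, whose actin and Gapdh probe sets had raised 3'/5' ratios (4.57 and 2.99), 88 and 96 without trigeminal array 1, and 77 and 79 without trigeminal array 2. Pomc was seen on trigeminal array 2 alone (7580 against 41.6) and was 0.00 without it. Qsox1, Acvrl1 and F2r lost the call without dorsal root ganglion array 1 or either trigeminal array, Acvrl1 and F2r also without dorsal root ganglion array 2. Tex261 lost it without dorsal root ganglion array 1 (2.10) or trigeminal array 2 (1.54). The differences of Qsox1, Acvrl1 and F2r stayed at 2.69 or more in these fits.

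Brown fat was compared with adipose tissue, the heat-producing against the storing depot. Ucp1, the uncoupling protein that makes heat, was at least 274-fold higher in brown fat (log2 8.10 ± 0.46 SE, adjusted p = 1.5e-19), at 13800 ± 2320 (SD, n = 2 arrays) against 28.4 ± 24 (n = 2). Cidea, a lipid droplet protein, was 74-fold higher (6.21 ± 0.49) and Cox7a1, a subunit of cytochrome oxidase, 59.6-fold (5.90 ± 0.73). The muscle genes Acta1 (120-fold) and Myh4 (58-fold) and the pigment enzyme gene Dct (at least 56.2-fold) were also higher. Cd52, a surface protein of lymphocytes, was at least 33.1-fold lower (-5.05 ± 0.50, adjusted p = 3.3e-11), with Igkv6-23 (33-fold), C1qc (at least 31.1-fold), Lyz2 (at least 30-fold), H2-Aa (29-fold) and Ctss (25.7-fold). Of 7 brown fat genes 6 rose on both scales (adjusted p = 3.1e-11), with Fabp3 at 3.99 ± 0.57. Of 59 genes of mitochondrial respiration 53 rose on both scales (adjusted p = 4.8e-40), with Atp5o at 2.98 ± 0.61 and Atp5k at 2.91 ± 0.61. All 12 fast skeletal muscle genes rose on both scales (adjusted p = 7.7e-10, or 0.048 with an estimated correlation). Of 12 B cell genes 7 fell and Ighd rose (2.89 ± 0.70) on both scales (adjusted p = 8.1e-04), with Cd79a at -3.94 ± 0.75. Retn (-2.17 ± 0.31) and Lep, or leptin (-1.10 ± 0.30), fell among 9 white fat genes on both scales (adjusted p = 0.73, list median 0.21 and mean -0.02). None of 6 pancreatic acinar genes passed on either scale (adjusted p = 0.96). In all 607 probe sets were higher and 753 lower, or 139 and 145 with the array-name series as a block, where Acta1 (log2 6.91 ± 1.20 SE before and 6.28 ± 2.82 in the block, adjusted p = 0.24), Myh4 (5.86 ± 1.08 and 5.21 ± 2.42), C1qc (-4.96 ± 0.73 and -3.94 ± 1.57) and Dct (5.81 ± 1.05 and 2.17 ± 2.46) lost the call. All but Dct kept most of the difference with a wider standard error.

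Heart and skeletal muscle separated along their contractile proteins. Tnni3, the cardiac troponin I, was at least 306-fold higher in heart (log2 8.26 ± 0.29 SE, adjusted p = 5.6e-29), at 15400 ± 1600 (SD, n = 2 arrays) against -166 ± 0.323 (n = 2), and Myh6, the alpha myosin heavy chain, 167-fold higher (7.38 ± 0.47). Atp2a2 (at least 152-fold), Tnnt2 (99.7-fold), Crip2 (at least 56.1-fold) and Csrp3 (at least 55.1-fold, adjusted p = 9.0e-46) were higher too. Myh4, a fast myosin heavy chain, was 339-fold lower (-8.41 ± 1.08), at 100 ± 79.5 against 30200 ± 4140 (SD, n = 2 arrays each). Ryr1, the calcium release channel of skeletal muscle, was at least 155-fold lower, with Pvalb (at least 150-fold), Tnni2 (at least 132-fold), Myoz1 (130-fold) and Myh1 (114-fold). Of 14 cardiac genes 12 rose on both scales (adjusted p = 2.1e-45), and all 12 fast skeletal muscle genes fell on both scales (adjusted p = 2.3e-21), such as Mylpf at -6.80 ± 0.92. Of 59 respiration genes 4 rose, among them Cox6a1 (1.45 ± 0.22), and 2 over the list alone (adjusted p = 0.0076, but adjusted p = 0.58 with an estimated correlation). Hba-a1 (2.49 ± 0.49) and Alas2 (1.79 ± 0.59) rose among 8 erythroid genes, 3 over the list alone (adjusted p = 0.076), and none of 8 smooth muscle genes passed on either scale (adjusted p = 0.73). In all 466 probe sets were higher and 452 lower, or 104 and 111 with the array-name series as a block, where Myh1 lost the call at -5.35 ± 1.88 (-6.83 ± 0.99 before, adjusted p = 0.14).

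Bone was compared with bone marrow to see what the skeleton adds to the marrow it holds. Col3a1, a fibrillar collagen, was 35.9-fold higher in bone (log2 5.16 ± 0.48 SE, adjusted p = 1.5e-11), at 2050 ± 220 (SD, n = 2 arrays) against 57.1 ± 6.04 (n = 2), and Postn, the matrix protein periostin, 21.3-fold higher (4.41 ± 0.37). The muscle genes Actn3 (49-fold), Pvalb (19.5-fold), Ryr1 (at least 18.5-fold) and Pgam2 (16.9-fold) were higher as well. The lower genes had low signals: Bmp15 was at least 5.52-fold lower (-2.46 ± 0.06, adjusted p = 8.6e-36), at -84.6 ± 27.9 against 279 ± 56 (SD, n = 2 arrays each), with Bpifa2 (5.92-fold), Wdr75 (at least 5.78-fold), Mmp12 (at least 5.66-fold), Mecom (at least 5.61-fold) and Ikzf1 (at least 5.4-fold). Sparc, or osteonectin, rose (1.92 ± 0.38) among 7 bone genes, 4 over the list alone (adjusted p = 2.9e-04), with Col1a1 at 15300 ± 1550 against 4960 ± 140 (SD, n = 2 arrays each). Of 12 fast skeletal muscle genes 10 rose and 12 over the list alone (adjusted p = 1.4e-20). Epor, the erythropoietin receptor, fell (-1.67 ± 0.13) among 8 erythroid genes on both scales (adjusted p = 9.3e-04), Bub1 (54.2 ± 11.9 against 113 ± 27, SD, n = 2 arrays each) among 19 proliferation genes on both scales (adjusted p = 0.0011) and Cd72 (-1.25 ± 0.33) among 12 B cell genes on both scales (adjusted p = 0.2). None of 12 granulocyte genes passed on either scale (adjusted p = 0.99, median 0, mean -0.05 and a set test pointing up), nor any of 7 cartilage genes (adjusted p = 0.44). In all 133 probe sets were higher and 69 lower, or 22 and 17 with the array-name series as a block, where only Col3a1, Postn, Mecom and Bmp15 of the 12 named genes kept the call. The others had wider standard errors. Pvalb stayed at 4.28 (± 0.68 before and ± 1.11 in the block, adjusted p = 0.056), Pgam2 at 4.08 (± 0.67 and ± 1.08) and Ikzf1 at -2.43 (± 0.57 and ± 1.02). Actn3 was at 5.38 ± 1.78, Ryr1 at 3.31 ± 1.18, Bpifa2 at -2.99 ± 1.17, Mmp12 at -1.83 ± 0.97 and Wdr75 at -1.75 ± 1.25. Without bone array 2 the counts were 49 and 30, and without bone marrow array 2 the higher count was 83. Wdr75 lost the call without any 1 array (-2.54 to -2.53), and Bpifa2 too (-2.93 to -2.20). Ikzf1 lost it without bone array 2 (-2.43) or either marrow array (-2.43 and -2.44), Mmp12 without bone array 2 (-2.50) or marrow array 1 (-2.23) and Mecom without marrow array 1 (-2.25). A floor of 20 ended the call of Bpifa2 (-2.57, adjusted p = 0.067), and a floor of 100 those of Wdr75 (-1.53, 0.076) and Mmp12 (-1.50, 0.092).

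Thymus and spleen set developing T cells against a mature lymphoid organ. Rag1, which joins antigen receptor segments, was at least 119-fold higher in thymus (log2 6.90 ± 0.13 SE, adjusted p = 2.7e-40), at 6060 ± 1500 (SD, n = 2 arrays) against -22.7 ± 10.4 (n = 2), and Dntt, which adds nucleotides at the joints, 33.2-fold higher (5.05 ± 0.31). Myb (41.3-fold), Srsf2 (at least 25-fold), Xrcc6 (at least 24.4-fold) and Cd8a, the coreceptor of cytotoxic T cells (at least 24.1-fold), were higher too. Ms4a1, the B cell antigen CD20, was at least 80.7-fold lower (-6.33 ± 0.33), and Cd79a of the B cell receptor 37-fold lower. The pancreatic enzyme genes Prss2 (75.5-fold) and Cela1 (at least 56.3-fold), the amylase gene Amy1 (at least 47.5-fold) and Tyms-ps (at least 51.1-fold) were also lower in thymus. Of 15 T cell genes 11 rose (adjusted p = 1.3e-29), of 19 proliferation genes 15 rose (adjusted p = 4.4e-15) and of 12 B cell genes 10 fell (adjusted p = 5.8e-10), with the same counts adjusted over the list alone. Thy1 was at 4.40 ± 0.44, Mki67 at 3.87 ± 0.50, Top2a at 3.70 ± 0.47 and Blk at -4.05 ± 0.65. Of 11 antigen-presentation genes 8 fell and 9 over the list alone (adjusted p = 5.7e-07), H2-Ab1 at -2.58 ± 0.47. Alas2 (-4.69 ± 0.59), Hba-a1 (-3.42 ± 0.49) and Slc4a1 (-3.32 ± 0.44) fell among 8 erythroid genes on both scales (adjusted p = 0.0017). Ucp1 rose (1.59 ± 0.46) as 1 of 7 brown fat genes on both scales (adjusted p = 0.54). In all 590 probe sets were higher and 475 lower, or 258 and 194 with the array-name series as a block, where Srsf2 (4.65 ± 0.84 before and 3.48 ± 1.34 in the block, adjusted p = 0.13) and Tyms-ps (-5.68 ± 1.51 and -4.40 ± 2.51) lost the call. The counts were 350 and 328 without spleen array 2, where Tyms-ps lost the call (-5.31, adjusted p = 0.062), and 364 and 311 without thymus array 1.

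Small and large intestine were compared as neighbouring parts of the gut. Apoa1, the main protein of high-density lipoprotein, was at least 383-fold higher in small intestine (log2 8.58 ± 0.36 SE, adjusted p = 1.0e-25), at 19200 ± 1320 (SD, n = 2 arrays) against -197 ± 144 (n = 2), with Apoa4 (at least 322-fold) and Fabp1 (at least 206-fold). The Paneth cell defensins Defa35 (at least 307-fold) and Defa23 (233-fold) and the brush border peptidase Anpep (at least 201-fold) were higher as well. Car1, a carbonic anhydrase, was at least 258-fold lower (-8.01 ± 0.13, adjusted p = 3.3e-44) and Retnlb, a goblet cell protein, at least 195-fold lower (-7.61 ± 0.28). The kallikrein genes Klk1b22 (128-fold), Klk1b5 (at least 99.7-fold), Klk1b1 (83.1-fold) and Klk1b16 (at least 53.3-fold) were lower too. Of 14 absorptive genes 11 rose and 2 fell on both scales (adjusted p = 3.0e-23): Mep1a, a meprin subunit (-3.26 ± 0.25), and Cdx1 (-0.94) went against Slc5a1 (5.27) and Lct (5.83). Of 6 Paneth and goblet cell genes 4 rose on both scales (adjusted p = 1.6e-05), with Reg3g at 6.30 ± 0.73, and of 5 large intestine genes 3 fell on both scales (adjusted p = 4.8e-06), with Aqp8 at -3.92 ± 0.51. Of 8 smooth muscle genes 4 fell on both scales (adjusted p = 0.088), with Cnn1 at -2.50 ± 0.84, and Cela1 fell (-3.32 ± 0.79) as 1 of 6 pancreatic acinar genes on both scales (adjusted p = 0.44). In all 635 probe sets were higher and 705 lower, or 176 and 180 with the array-name series as a block. Both counts were 321 without large intestine array 1, whose actin and Gapdh probe sets had 3'/5' ratios of 4.39 and 1.66.

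Epidermis and snout epidermis were compared as body and facial skin. Krt2, a keratin of the upper epidermis, was 38-fold lower in epidermis than in snout epidermis (log2 -5.25 ± 0.11 SE, adjusted p = 2.2e-39), at 96.2 ± 36.6 (SD, n = 2 arrays) against 3520 ± 50.3 (n = 2). Cidea (at least 16.6-fold), Aldh3a1 (15.4-fold), Dhrs7 (at least 11.3-fold), Psmb6 (at least 7.92-fold) and Efnb1 (at least 7.84-fold) were lower as well. Mup5, a major urinary protein, was at least 37.9-fold higher (5.24 ± 0.71) and Cyp2e1, a cytochrome P450 enzyme, 19.7-fold (4.30 ± 0.72), with Ifitm6 (at least 18.2-fold), Actn3 (17.8-fold), Mup3 (12.9-fold) and Nr4a2 (at least 8.18-fold). Retn (2.57 ± 0.31), Adipoq (2.38 ± 0.63) and Fabp4 (2.24 ± 0.44) rose among 9 white fat genes, 4 over the list alone (adjusted p = 7.8e-04), while Cidea and Elovl3 (-1.03 ± 0.30) fell among 7 brown fat genes on both scales (adjusted p = 0.0025). Flg fell (-2.67 ± 0.50) among 18 keratinocyte genes, 2 over the list alone (adjusted p = 0.032, but 0.22 with an estimated correlation). Foxn1 fell (-1.99 ± 0.60) among 7 hair genes on both scales (adjusted p = 0.024, but 0.095 with an estimated correlation). Actn3 and Pvalb (1.97 ± 0.48) rose among 12 fast skeletal muscle genes, 3 over the list alone (adjusted p = 9.1e-04, but adjusted p = 0.3 with an estimated correlation). In all 146 probe sets were higher and 111 lower, but 56 and 53 without snout array 1, 73 higher without epidermis array 1 and 86 higher without epidermis array 2. Psmb6 lost the call without any 1 array (-3.14 to -2.83), Nr4a2 without either snout array (3.03 in both) or epidermis array 1 (2.73) and Actn3 without snout array 1 (3.47) or epidermis array 2 (3.74), or with a floor of 20 (4.15, adjusted p = 0.11).

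Testis and ovary differed more than any other pair. Tnp2, a transition protein of condensing sperm chromatin, was at least 410-fold higher in testis (log2 8.68 ± 0.53 SE, adjusted p = 2.3e-19), at 20500 ± 852 (SD, n = 2 arrays) against -332 ± 305 (n = 2). The sperm-specific glycolytic genes Gapdhs (at least 249-fold) and Ldhc (at least 219-fold), the protamine Prm1 (161-fold), Gsg1 (at least 167-fold) and Crisp2 (at least 143-fold, adjusted p = 1.5e-61) were higher too. Hsd3b1, a steroid dehydrogenase, was at least 99.8-fold lower (-6.64 ± 0.70) and Ovgp1, the oviduct glycoprotein, at least 101-fold lower. Acta2 (93.6-fold), Apoe (at least 68.7-fold), Col1a2 (at least 61.4-fold) and Mgp (53.8-fold) were also lower. All 18 testis genes rose on both scales (adjusted p = 8.0e-43). Inha, the inhibin alpha subunit (-5.45 ± 0.06), and Zp3 of the egg coat (-2.14 ± 0.23) fell among 6 ovary genes on both scales (adjusted p = 0.0037, but adjusted p = 0.075 with an estimated correlation). Of 19 proliferation genes 8 rose and Mcm3 fell (-0.80), or 10 and 1 over the list alone (adjusted p = 0.0013), Cdc20 at 3.56 ± 0.72 and Aurka at 3.53 ± 0.22. Hsd3b1 and Cyp11a1 (-3.75 ± 0.36) fell among 9 adrenal genes on both scales (adjusted p = 0.11). Xist, the RNA of the silenced X chromosome, fell (-3.50 ± 0.59) and Eif2s3y was at 1.13 ± 0.46, 1 lower and 1 higher over the list alone (adjusted p = 0.62). In all 876 probe sets were higher and 1174 lower.

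Placenta and umbilical cord are both conceptus tissue of late pregnancy. Tpbpa, a trophoblast protein, was 173-fold higher in placenta (log2 7.43 ± 0.24 SE, adjusted p = 4.6e-31), at 13700 ± 3010 (SD, n = 2 arrays) against -97 ± 311 (n = 2). The placental prolactins Prl8a6 (149-fold) and Prl8a2 (at least 130-fold), the pregnancy-specific glycoprotein genes Psg16 (139-fold) and Psg-ps1 (at least 111-fold) and Tfpi2 (89.7-fold) followed. In the other direction, Krt10 was at least 114-fold lower in placenta (-6.83 ± 0.87), Cnn1, or calponin, at least 61.1-fold, Krtdap at least 53.7-fold, Vwf, or von Willebrand factor, at least 51.4-fold, Col6a2 54.7-fold and Eln, or elastin, 44.8-fold. Of 10 placental genes 9 rose and 10 over the list alone (adjusted p = 1.3e-35), with Prl7d1 at 4.45 ± 0.06. Of 14 imprinted genes 6 fell and Peg10 rose (4.30 ± 0.44) on both scales (adjusted p = 1.3e-04), with Ndn at -2.98 ± 0.22 and Plagl1 at -2.70 ± 0.53. Of 10 matrix genes 7 fell on both scales (adjusted p = 3.7e-11), with Postn at -3.73 ± 0.37. None of 8 erythroid genes passed on either scale (adjusted p = 0.9). In all 562 probe sets were higher and 498 lower.

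Each of the 10 CNS regions was set against the mean of the other 9, n = 2 arrays against 9 tissue means, which gave 1115 higher calls. In cerebellum (184 probe sets) Gabra6, the GABA receptor subunit of granule cells, was at least 47.5-fold higher (log2 5.57 ± 0.08 SE, adjusted p = 5.4e-47), Car8 of Purkinje cells 45-fold and Zic1 28.6-fold. In hypothalamus (83) the neuropeptide genes Avp, or vasopressin (at least 46.3-fold, adjusted p = 1.0e-60), Oxt, or oxytocin (44.1-fold), and Hcrt, or orexin (14.9-fold), led. In olfactory bulb (126) Dlx1, a transcription factor of interneurons, was at least 19.2-fold higher (4.26 ± 0.03), with Inpp5j (17-fold) and S100a5 (16.8-fold). Ngef (13.6-fold), Cacna2d3 (9.54-fold) and Pde1b (7.63-fold) led in striatum (100), and Ccn3 (6.39-fold), Wfs1 (5.83-fold) and Gria3 (4.79-fold) in amygdala (96). In hippocampus (75) Ttr, or transthyretin, made by choroid plexus, was 8.14-fold higher (3.02 ± 0.33), with Igf2 (6.47-fold) and Nrgn, the calmodulin-binding neurogranin of dendrites (5.57-fold). Frontal cortex (37) was led by Nrgn (7.43-fold), Ngef (4.94-fold) and Mef2c (4.76-fold), and cortex (104) by the gland genes Mucl2 (153-fold), Scgb1b27 (115-fold) and Prol1 (24.7-fold). In the upper cord (141) Mag, a myelin protein, was 10.5-fold and Vamp1 10.1-fold higher, with Acta1 at 5680 ± 7430 (SD, n = 2 arrays) against 953 ± 2500 (n = 9 tissues). In the lower cord (169) Acta1 (52.4-fold), S100a9 (26.9-fold) and Col1a2 (20.4-fold) led. Leaving out 1 array moved several counts by over 1.5 times: lower cord 68 without array 1, upper cord 78 without array 1 (where Acta1 was at 1.49, adjusted p = 0.99), hypothalamus 47 and 51 without array 1 or 2, striatum 65, olfactory bulb 66 and hippocampus 49 without array 1, cortex 64 and amygdala 55 without array 2. With the array-name series as a block the calls came to 501, and the count dropped by over 1.5 times in hippocampus (13), amygdala (14), cortex (27), hypothalamus (54), lower cord (55), striatum (56), olfactory bulb (61) and upper cord (63). In that fit Igf2 (4.31 ± 1.07, from 2.69 ± 0.47) and Nrgn (2.75 ± 0.99, from 2.48 ± 0.42) in hippocampus and Acta1 in upper cord (3.59 ± 1.38, from 3.82 ± 0.90) lost the call at a wider standard error, and Gria3 in amygdala at a smaller difference (1.04 ± 0.27, from 2.26 ± 0.19).

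Each tissue was then set against the mean of the other 44. Of 7623 probe sets 3704 were enriched in at least 1 tissue, 1622 of them in exactly 1, with a median of 199 per tissue. Liver had 409, testis 401, gall bladder 340, small intestine 336 and bone marrow 297, and tongue epidermis (118) and ovary (91) the fewest. The gene with the largest fold was Alb, or albumin, in liver (388-fold), Myl2 in heart (305-fold), Myh4 in skeletal muscle (191-fold), Atp4b of the acid pump in stomach (at least 351-fold), Miox in kidney (at least 215-fold), the secretoglobin Scgb1a1 in lung (455-fold) and trachea (313-fold), and Cryaa, a lens crystallin, in eye (at least 362-fold). Csn1s1, a casein, was 512-fold higher in mammary gland, Tnp2 363-fold in testis, Tpbpa 264-fold in placenta, Sbp 371-fold in prostate and Ovgp1 98.7-fold in ovary. Hsd3b1 led in adrenal gland (104-fold), Ucp1 in brown fat (173-fold), Retn in adipose tissue (93.9-fold), Glycam1 in lymph node (89-fold), Rag1 in thymus (110-fold), Ms4a1 in spleen (57.8-fold) and Ngp in bone marrow (221-fold) and bone (233-fold). Krt10 led in digits (220-fold), snout epidermis (157-fold) and epidermis (152-fold), Krtdap in tongue epidermis (113-fold), Sprr2f in uterus (81.4-fold), Gsta4 in bladder (53.1-fold), Igf2 in umbilical cord (201-fold), Smr3a in salivary gland (499-fold), Fxyd2 in dorsal root ganglion (64.9-fold) and Car1 in large intestine (222-fold). Some leaders belonged to another organ: Alb in gall bladder (244-fold), Prl in trigeminal (115-fold), Mucl2 in cortex (112-fold) and the salivary kallikrein gene Egfbp2 in thyroid (602-fold). Ngef led in striatum (57.9-fold), Zic1 in cerebellum (80.7-fold), Defa35 in small intestine (286-fold), Avp in hypothalamus (at least 46.3-fold), Gad1 in olfactory bulb (56.5-fold), Mobp in the upper (59.6-fold) and lower cord (41.3-fold), Snap25 in frontal cortex (35.2-fold), Ncdn in hippocampus (34.2-fold) and Gria2 in amygdala (28-fold). Without salivary gland array 1 that tissue had 354 in place of 178, without large intestine array 2 it had 407 in place of 241, and without ovary array 2 ovary had 141. A floor of 100 lowered the count by over 1.5 times in 15 tissues. The highest of these counts were 188 in bone marrow and 156 in bone, and the lowest 83 in uterus and 99 in lower cord. Lower cord had 100 with the array-name series as a block.

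**Figure D2:**
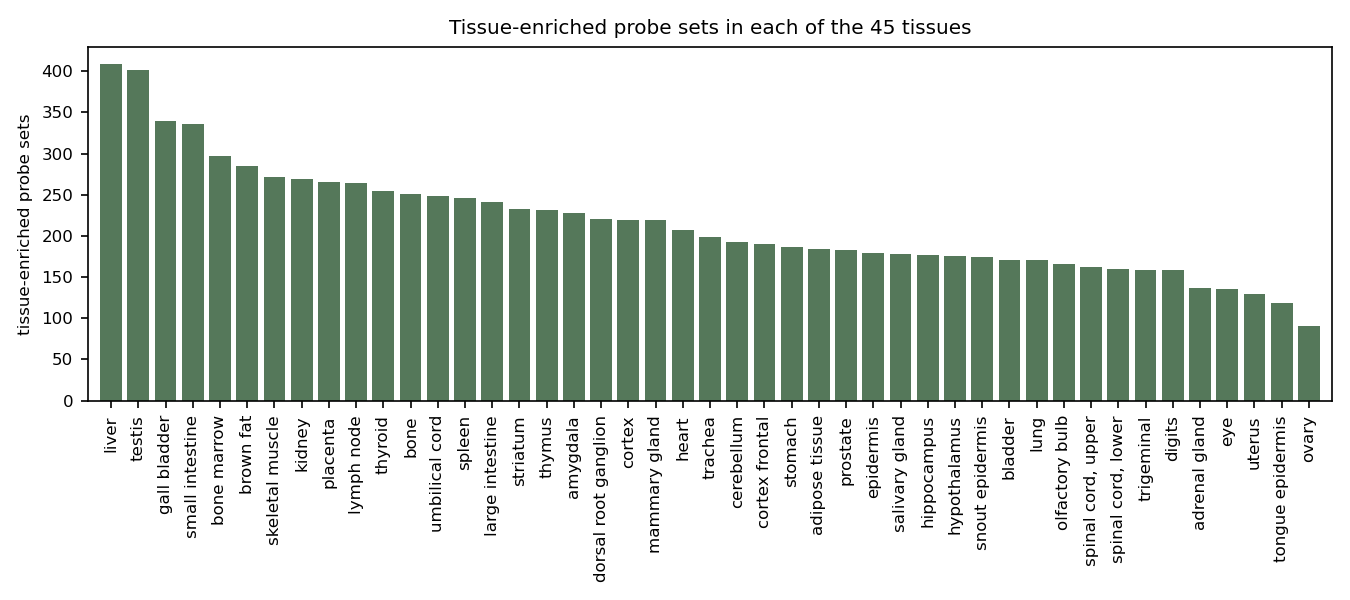
Number of tissue-enriched probe sets (bars, vertical axis) in each of the 45 tissues (horizontal axis), from liver with 409 to ovary with 91. A probe set is enriched at an adjusted p below 0.05, a log2 difference of at least 2 from the mean of the other 44 tissues and a mean signal of at least 200.

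Marker lists fixed in advance were looked up in their own tissue. Members were counted as higher at an adjusted p below 0.05 and as enriched at a log2 difference of at least 2 and a signal of at least 200. All members were enriched for kidney (10), mammary gland (11), testis (18), skeletal muscle (12), eye (12), prostate (6) and bladder (3). For liver 13 of 14 were higher and 13 enriched, for heart 13 of 14 and 12, for placenta 10 of 10 and 9, for cerebellum 9 of 10 and 9, for adrenal gland 9 of 9 and 8 and for stomach 7 of 7 and 6. In thymus 14 of 15 T cell genes were higher and 11 enriched, and in bone marrow 11 of 12 granulocyte genes and 11. Of 18 keratinocyte genes 12 were higher, 1 lower and 9 enriched in epidermis, and 13, 2 and 9 in snout epidermis. Of 12 B cell genes 11 were higher and 6 enriched in spleen. All 6 sensory neuron genes in dorsal root ganglion, cortical and hippocampal genes in hippocampus and olfactory bulb genes were higher and 3 of each enriched. The counts were 6 of 7 and 3 for bone, 4 of 5 and 2 for large intestine and uterus, 4 of 6 and 2 for ovary and 2 of 3 and 1 for airway in trachea. In thyroid 0 of 2 tested genes were higher, with the hormone precursor gene Tg at its highest in stomach, at 57 ± 34.1 (SD, n = 2 arrays). In the 6 tissues labelled as a single sex, Xist was at 1190 and 267 on the ovary arrays, 830 and 657 in uterus, 718 and 987 in mammary gland and 117 and 480 in placenta, against 6.77 and 55.3 in prostate and 20.9 and 33.8 in testis. The Y-linked gene Eif2s3y reached 200 in 35 tissues, with 208 in uterus and 288 in mammary gland, and Uty and Kdm5d in none.

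Arrays of several tissues carried abundant transcripts of another organ, given here as measured. Gh was at 16600 and 23200 and Prl at 4200 and 17600 on the trigeminal arrays. On the thyroid arrays Klk1 was at 33500 and 31500, Egf, or epidermal growth factor, at 28900 and 26000 and Mucl2 at 41800 and 33500, and on the cortex arrays Mucl2 was at 8220 and 9290. The pancreatic elastase gene Cela1 was at 4980 and 1590 on the spleen arrays and at 9.32 and 5510 on the ovary arrays. Alb was at 20400 and 14500 in gall bladder against 24900 and 29600 in liver, and Scgb1a1 at -71 and 14300 in tongue epidermis.

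**Figure D3:**
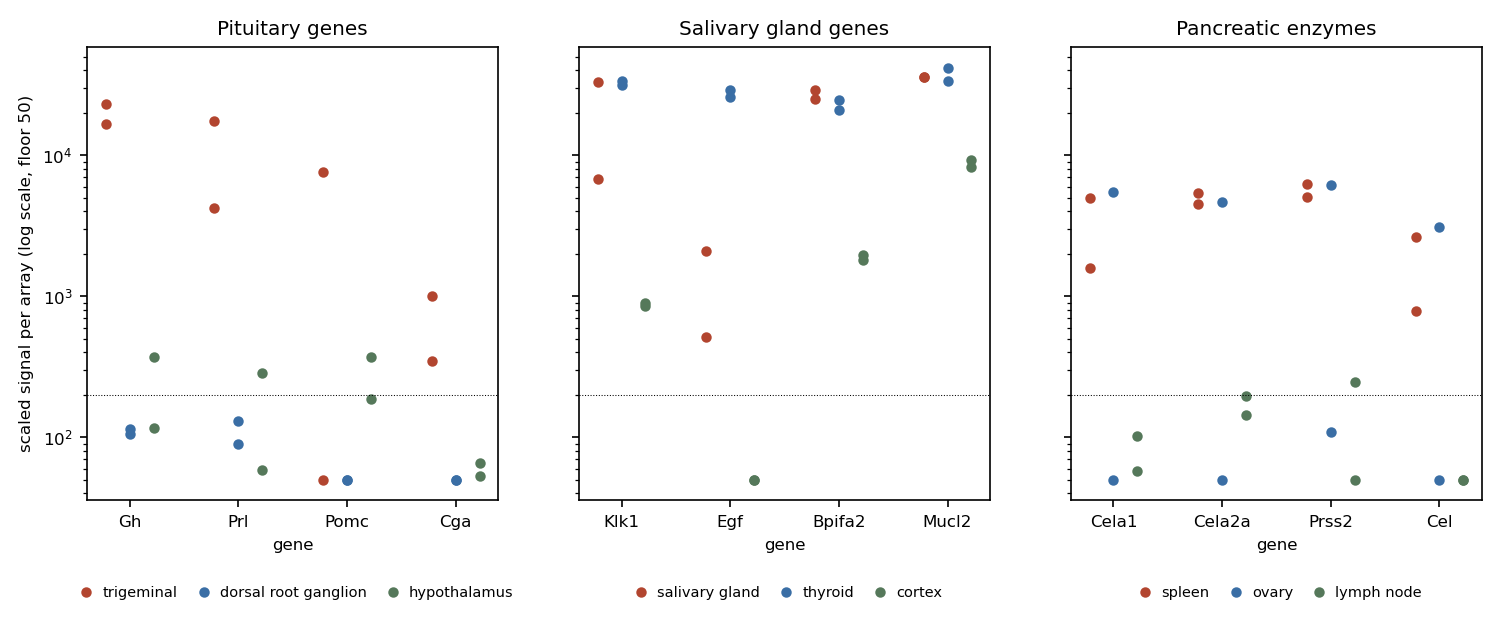
Scaled signal per array (vertical log axis, values below the floor drawn at 50; each dot is 1 of 2 arrays) of pituitary, salivary gland and pancreatic enzyme genes in 3 tissues each; the dotted line marks 200. Gh on trigeminal arrays reached 16600 and 23200, Mucl2 on thyroid arrays 41800 and 33500, and Cela1 on ovary arrays 9.32 and 5510.

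Breadth of expression was counted over all 9977 non-control probe sets as the number of tissues with a mean signal of at least 200. In no tissue did 2354 reach it, 862 reached it in exactly 1, 2336 in 1 to 5, 2048 in 40 or more and 1239 in all 45, with a median of 7 tissues. Probe sets at 200 in 1 tissue and below 100 in all others were most frequent in testis (54, with Gapdhs and Ldhc the brightest genes), placenta (18, Tpbpa and Prl8a6), eye (14, Cryaa and Crybb2) and kidney (12, Miox and Slc22a6), then mammary gland and thymus (11 each) and stomach (9, Atp4b). Of 1710 values from 19 control probe sets for bacterial and yeast genes, 5.03 percent reached 200, against 35.7 percent of all other values, so a signal of 200 is a level and not a detection call. At a level of 100, 1354 probe sets were in no tissue and 2134 in all 45.

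**Figure D4:**
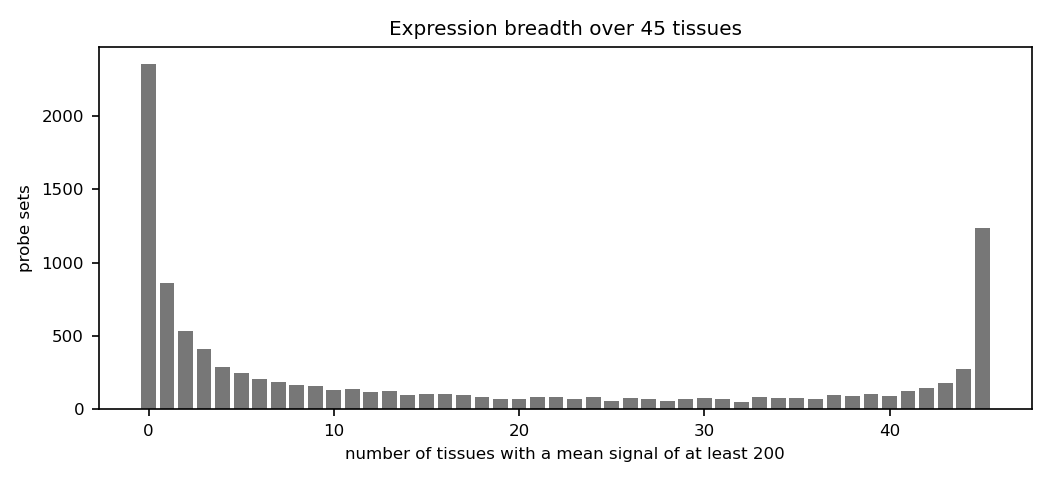
Number of probe sets (vertical axis) by the number of tissues with a mean signal of at least 200 (horizontal axis, 0 to 45). The bar at 0 holds 2354 probe sets and the bar at 45 holds 1239.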

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

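The tests on pituitary, salivary and pancreatic transcripts and the criterion for control probe sets were chosen only after the values were seen, while the splits of the tissues were planned.

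Cyba, a subunit of the phagocyte oxidase, lay far from the others in spleen among the 4 lymphoid and marrow tissues, with a gap of 0.941 of their range. The search covered 20 genes, the named genes higher in CNS or in lymphoid tissues, found this 1, and finds about 5 percent by chance. A control probe set for the opposite strand of the bacterial gene bioB (AFFX-BioB-5_st) read 5506 on snout epidermis array 1, against a second highest of 468 and a median of 188 over 90 arrays, and AFFX-BioB-M_st read 2297 on the same array. These controls enter no comparison, and no explanation was tested for either result.

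Pituitary hormone genes were bright on the trigeminal arrays, with Gh at 16600 and 23200 and Prl at 4200 and 17600. Of 8 pituitary list members, 5 had their highest tissue mean in trigeminal, and of Gh, Prl, Pomc and Cga 0 of 4 reached 200 in dorsal root ganglion, which argues against expression of these 4 genes by sensory neurons shared by both ganglia. Pituitary RNA carried into the sample may explain the pattern, since the gland lies beside this ganglion. Expression particular to trigeminal neurons was not tested and stays open.

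Salivary genes were bright on the thyroid arrays, with 8 of 9 list members at 200 or more and at 10 percent or more of the salivary gland mean, though Smr2 and Prol1 reached 200 in all 45 tissues. Of the 9, Amy1 and Bpifa2 had a lower mean in thyroid than in salivary gland and the others a higher one, such as Klk1b16 (29300 against 6490). Salivary gland array 1 was closest to a thyroid array. Carried-in salivary RNA may explain the pattern, but not alone the higher thyroid means. Mucl2 and Bpifa2 (25158 or more on salivary gland arrays) cannot decide on a label exchange, being bright on thyroid arrays too. Whether the thyroid samples held thyroid RNA cannot be told apart from unresponsive probe sets, because Tg, Tshr and Pax8 reached no more than 67.3 in thyroid and 155 in any other tissue. No biological explanation was tested.

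Pancreatic enzyme genes were bright on the spleen arrays and on ovary array 2, where 6 of 6 acinar list members reached 200 and none did on ovary array 1. Expression by lymphoid cells is argued against by 0 of 6 members at 200 in thymus, lymph node and bone marrow alike. None reached it in thymus or lymph node, while Cela2a did in bone marrow (790 ± 416, SD, n = 2 arrays) and in 20 tissues in all. Pancreas RNA carried into the samples may explain the pattern, and no pancreas was sampled to compare with. Expression by spleen alone stays open for the spleen arrays.

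Splits of the same tissues into groups of the same sizes were planned to exclude chance where less than 5 percent of them called as many probe sets. For CNS 1 of 100 splits called as many probe sets, the real one with 1136, against a highest other of 136. For ganglia it was 1 of 66 (327 against 40) and for lymphoid tissues 1 of 100 (445 against 155). This excluded chance for these 3 comparisons. For digestive tract 4 of 100 splits called as many (112 against 230), and for epidermal tissues 3 of 100 (96 against 176). Both are under 5 percent, but another grouping, whose tissues were not examined, called more than the real one, so chance stays open.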

How the results depend on the processing

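The series as covariates and the fits without tissues or arrays that stood apart were chosen after the values were seen, and all other settings were planned. Values as deposited, quantile normalization, no filter and no mean trend kept every comparison's counts within 1.5 times. Of the named genes these ended the call of 0, 1 (Hp), 6 and 0. Signals near the floor limit the lower side of most folds. Replicate agreement had no test. No paired analysis was possible because the labels give no replicate numbers. Where 1 array of a tissue was left, it was assumed to vary like the other groups. The cause was not tested for any change below, except that leaving out samples lowers their number and that the series in the model widened the standard error of most lost calls.

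With a floor of 20, the lower counts were 20 for digestive tract and 2 for epidermal tissues, spinal cord had 5 higher and 7 lower, and cortex against frontal cortex 19 higher. With a floor of 100, the lower counts were 310 for CNS, 46 for lymphoid tissues, 0 for epidermal tissues and 21 for cortex. With the array-name series as a block, higher and lower counts were 29 and 26 for dorsal root ganglion against trigeminal, where Acvrl1 turned to -0.41, 139 and 145 for brown fat, 104 and 111 for heart, 22 and 17 for bone, 258 and 194 for thymus, 176 and 180 for small intestine, 25 lower for cortex and 501 over the CNS regions. With arrays as replicates they were 412 and 375 for ganglia, 603 and 475 for lymphoid tissues, 482 and 350 for digestive tract and 356 and 145 for epidermal tissues.

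With the series as covariates they were 48 and 0 for digestive tract and 60 and 0 for epidermal tissues. Without thyroid, gall bladder, ovary and spleen the lymphoid lower count was 28, and without tongue epidermis array 2 the epidermal lower count was 3. At a signal level of 100, 1354 probe sets reached it in no tissue, 568 in exactly 1 and 2134 in all 45, and at a level of 400, 4103 in none and 512 in all 45.

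Leaving out 1 tissue, 1 array or 1 replicate of every tissue gave these ranges of higher and lower counts: ganglia 119 to 222 and 61 to 126, digestive tract 5 to 25 lower, lymphoid tissues 32 to 61 lower, epidermal tissues 50 to 88 and 0 to 1, spinal cord 4 to 18 and 7 to 59, dorsal root ganglion 53 to 132 and 53 to 144, bone 49 to 161 and 30 to 103, thymus 350 to 722 and 311 to 576, small intestine 321 to 831 and 321 to 890, and epidermis 56 to 99 and 53 to 90. Ngp in spinal cord ran from -4.97 to 0. Among named genes, lists, regions and tissues, 1406 such results stayed, 134 lost the call, and Ngp lost it at a difference of 0. With a floor of 20, 531 stayed and 12 lost it, and with a floor of 100, 516 stayed and 11 lost it. With the series as a block 313 stayed, 29 lost it in the same direction, and Acvrl1 lost it in the other.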

Other observations

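No test was run on the values in this part, and the genes were picked from lists fixed in advance after their values were seen.

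Imprinted genes, expressed from the allele of a single parent, were highest in conceptus tissue and in a few adult tissues. Igf2, a fetal growth factor, was at 15900 ± 2850 (SD, n = 2 arrays, as for all values here) in umbilical cord and 12800 ± 2310 in placenta, and Cdkn1c, a cell cycle inhibitor, at 8900 ± 319 and 5490 ± 790. Plagl1 (3800 ± 44.8) and Dlk1 (4170 ± 255) were also highest in umbilical cord, and Peg10 was highest in placenta (1870 ± 249). Hypothalamus had the highest Ndn (3930 ± 7.2) and Nnat (4200 ± 420), and brown fat the highest Gnas (21500 ± 1360). All 14 measured members of the list reached 200 in at least 1 tissue. Of the posterior Hox genes, which pattern the hind body, Hoxb13 was highest in prostate (1140 ± 423) and Hoxa11 and Hoxa10 in uterus (699 ± 92.2 and 282 ± 58.5). Hoxd10 was highest in thyroid (547 ± 142), Hoxc9 in upper cord (408 ± 10.1), Hoxa9 in digits (280 ± 19.4) and Hoxa13 in dorsal root ganglion (220 ± 30.6). The anterior Hox genes Hoxa4 and Hoxb8 read above 200 in all 45 tissues.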
